A study of Mus musculus with 17 samples.

How the data were processed

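RNA from sorted hematopoietic stem cells (HSCs) of mice was measured on 17 Affymetrix arrays in 5 groups. Per the labels' protocols, adult HSCs were sorted as lineage-negative, Sca-1-positive, c-Kit-positive, CD150-positive and CD48-negative cells, and fetal liver HSCs with low Mac-1 in addition. The groups were fetal liver at E15.5 (n = 3), control and C/EBPa knockout (KO) at day 7 after pIpC (n = 3 each) and control and KO at day 21 after pIpC (n = 4 each). Per the labels' protocols, total RNA was isolated with a column kit, amplified with the Ovation Pico WTA System V2 and biotinylated before hybridization. The labels do not say whether replicates came from separate animals or pools, so p-values measure the spread between these samples.

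Groups were taken from the sample titles, which name the C/EBPa knockout. The genotype field of the adult samples and the design text name a PU.1 knock-in instead, so the labels conflict. For this reason Cebpa and Spi1, the genes for C/EBPa and PU.1, are reported on every array before any comparison. Whether the Cebpa probe set lies within the excised sequence is not given in the sources used here.

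The deposited values were intensities on a linear scale, 1 per probe set, for 45101 probe sets. RMA is the one tool that the submitters' processing notes name, without a role or version, and the authors' steps after it are not given in the sources used here. The lowest deposited intensity was 16 on every array, and 20.4% to 25.2% of probe sets per array lay at this floor. Median intensity per array ranged from 39.4 to 53.1. The columns did not share identical quantiles, and the scaling the authors used stays unknown. The test had been planned for values on a log2 scale; log2 of the deposited intensity was therefore taken, with no pseudocount, and the floor is 4 on this scale. A gene at the floor has only an upper bound, and a change against a group at the floor on all its arrays is a lower bound. Arrays give no count depth, and the number of arrays limits the precision.

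Probe sets were named through the platform annotation given with the value table. It listed 35890 probe sets, of which 34958 had 1 gene and 932 had several; 9160 probe sets other than controls were unnamed here. Identifiers of 34754 probe sets matched a mouse RefSeq gene table of assembly GRCm38.p6, used for names only. The probe set with the highest mean over the 17 arrays stood for each gene, which gave 18193 genes. Of these, 1409 lay at the floor on all arrays and 16784 were tested. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.952.

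A linear model with 1 mean per group was fitted to all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual df 12, prior df 1.5), without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were KO against control at each day, fetal liver against the mean of both adult control groups, control at day 21 against day 7, and the difference between the KO effects of both days. All adjusted p-values for genes are limma's. The 25 gene lists were fixed before the data were examined, as were the groups, tests and alternatives; they held 626 entries, of which 563 were measured above the floor on at least 1 array. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. As another question, fry tested each list against no change. Fetal effects were set against KO effects of the other day, so that no control array entered both sides. From 100 simulations of unchanged groups came a value for shared controls. They drew genes independently, with 1 spread per gene for all groups.

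Named genes followed a rule fixed before the data were examined. Cebpa, Spi1 and Mycn were always named for the first 3 comparisons, with the 6 largest called rises and falls whose groups did not overlap and whose higher mean exceeded the median probe set, and up to 2 called members per list. Where no gene passed in a direction, the 3 with the smallest p were given as values. For control day 21 against day 7 and for the interaction the limits were 4 genes and 1 member per list. Members of lists named beyond this rule were those with the smallest p in the list's direction, unless stated otherwise, and were chosen after their values were seen.

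The model was tested on simulated data, with the mean and spread of each of the 16784 genes and 200 changed genes. These 200 were drawn from genes above the median probe set, and 50 further genes were shifted by 1 on the log2 scale. All groups had the same spread for a gene. Recovery of dim genes, or with groups of unequal spread, was therefore not measured. At day 7 it recovered 40.3% of 4-fold changes and 83.3% of 16-fold changes; at day 21 it recovered 56.7% and 87.9%. For fetal liver against adult control it recovered 52.2% and 84.8%. Of 2-fold changes 10.4%, 23.9% and 11.9% were recovered in these 3 comparisons, with 8, 11 and 8 false calls. Alternatives covered the choice of probe set, filters on dim genes, scaling, moderation, array weights, replicate number, the ratio of 3' to 5' control signals and each array of the compared groups left out. Leaving out the array farthest from its group in each control group, and a covariate for the share of probe sets at the floor, were added after the data were seen. Scan dates were not used here, so batches were not tested.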

Results

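The arrays measured transcripts in HSCs sorted from fetal liver at E15.5 and from adult mice at day 7 or day 21 after pIpC, a synthetic double-stranded RNA that elicits interferon and is widely used to switch on an inducible Cre. There were 3 fetal liver, 3 control and 3 KO arrays at day 7, and 4 control and 4 KO arrays at day 21. The series title asks how the transcription factor C/EBPa acts on adult HSC quiescence. The sample titles name a C/EBPa knockout, whereas the genotype field and design text name a PU.1 knock-in.

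Cebpa, the gene for C/EBPa, was low on all 7 arrays titled KO. Mean intensity was 198 ± 102 (SD, n = 3) in control and 27.9 ± 6.26 (SD, n = 3) in KO at day 7, and 260 ± 197 (SD, n = 4) and 30.4 ± 6.64 (SD, n = 4) at day 21. The lowest control array stood at 115 and the highest KO array at 39.8. Fetal liver HSCs had 50.5 ± 26.9 (SD, n = 3). The log2 difference between KO and control was −2.73 (SE 0.55, adjusted p = 0.316) at day 7 and −2.82 (SE 0.48, adjusted p = 0.0536) at day 21. Neither passed the threshold over all genes, although the groups did not overlap at either day. Cebpa had been named before the data were examined. Its unadjusted limma p was 2.3e-04 at day 7 and 4.4e-05 at day 21. Chance gives such a separation in 10% of cases for 3 against 3 arrays and 2.86% for 4 against 4. Spi1, the gene for PU.1, differed by 0.34 (SE 0.47) at day 7 and −0.03 (SE 0.41) at day 21, with overlapping groups. Its 95% confidence intervals ran from −0.67 to 1.34 and from −0.90 to 0.85.

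**Figure D1:**
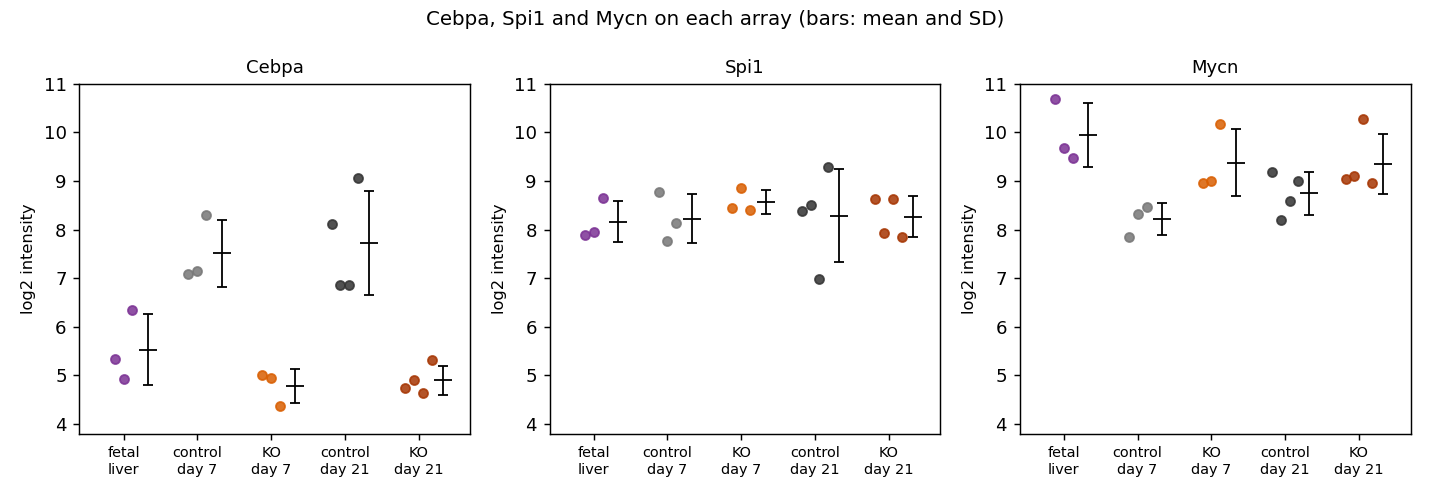
Log2 intensity (vertical axis) of Cebpa, Spi1 and Mycn on each of the 17 arrays, by group (horizontal axis). Points are arrays, and bars beside them give the group mean and SD. All 7 KO arrays lie below all 7 adult control arrays for Cebpa, and the Spi1 groups overlap.

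At day 7 the G2/M and erythroid lists had the highest medians in KO relative to control, and quiescence and p53 target genes the lowest, although no single gene was called. Of 53 measured G2/M genes, whose transcripts peak in G2 or mitosis, 48 were higher in KO, with a median log2 change of 0.91 (camera adjusted p = 8.4e-14; adjusted p = 0.0808 with an estimated correlation). No member passed over all genes and 7 were higher when adjusted over the list alone. Among these, Ncapd2, a condensin subunit, had a change of 2.48 (SE 0.43; −0.03 on its other, dimmer probe set), Cdc20, an activator of the anaphase-promoting complex, 2.74 (SE 0.54), and Cenpe, a kinetochore motor, 2.85 (SE 0.62). Of 37 G1/S genes, 31 were higher, with a median of 0.57 (camera adjusted p = 1.0e-05; adjusted p = 0.0815 with an estimated correlation). E2f8 was the one member that passed over the list alone, at 2.63 (SE 0.65). The nuclear genes of the respiratory chain were higher in 33 of 36, with a median of 0.52 (camera adjusted p = 2.2e-10; adjusted p = 0.0815 with an estimated correlation). Atp5o, a subunit of ATP synthase, had a change of 1.53 (SE 0.30) and Cox5a, of cytochrome c oxidase, 1.16 (SE 0.29), and 5 members passed over the list alone.

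Quiescence genes had a median of −0.36 at day 7, with 4 of 23 higher (camera adjusted p = 0.00718; adjusted p = 0.141 with an estimated correlation), and p53 targets −0.31, with 8 of 21 higher (camera adjusted p = 0.0149; adjusted p = 0.0815 with an estimated correlation). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 and belongs to both lists, had a change of −1.87 (SE 0.34, adjusted p = 0.268), with groups that did not overlap, and −1.19 on its other probe set. Plk2, another p53 target, had −1.85 (SE 0.50). Both passed when adjusted over the p53 list alone. Without control replicate 3 the p53 list lost its call, with a median of −0.19 and adjusted p = 0.102.

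Erythroid genes were higher in KO at day 7 in 19 of 20, with a median of 0.67 (camera adjusted p = 9.4e-06; adjusted p = 0.0815 with an estimated correlation). Their members included Klf1, an erythroid transcription factor, at 2.96 (SE 0.85), and Gata1 at 2.21 (SE 0.81). Megakaryocyte genes were higher in 16 of 19, with a median of 0.53 (camera adjusted p = 0.00292; adjusted p = 0.0956 with an estimated correlation), and Pf4, a platelet chemokine, had a change of 3.97 (SE 1.04). Pf4 alone passed when adjusted over that list. Multipotent progenitor genes, which mark cells outside the sort gate, had a median of 0.51 (camera adjusted p = 0.0125; adjusted p = 0.215 with an estimated correlation). Cd48, whose product the gate excludes, had a change of 2.78 (SE 1.04, adjusted p = 0.645). That list lost its call without KO replicate 3 (median 0.15, adjusted p = 0.345) or without control replicate 1 (median 0.25, adjusted p = 0.208). Ribosomal proteins had a median of 0.06 (camera adjusted p = 0.00718; adjusted p = 0.304 with an estimated correlation), which lay at −0.0030 when each array was centred on its median, with no call. Their call was also lost without KO replicate 1 (adjusted p = 0.0518) or control replicate 2 (adjusted p = 0.0614), and that of the progenitor list with the share of probe sets at the floor as a covariate (median 0.32, adjusted p = 0.0692).

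Over all 16784 genes limma called 0 at day 7, with a smallest adjusted p of 0.268, and 1128 had an unadjusted p under 0.05 where chance gives 839. The unmoderated linear model also called 0. The smallest p-values belonged to Synpo2, at 2.40 (SE 0.41; 0.74, 0.58 and −0.21 on its other 3 probe sets), Ncapd2, and Nlrp3, an inflammasome sensor, at 0.80 (SE 0.14), among positive values. Among negative values they belonged to 4833407H14Rik, at −3.01 (SE 0.51), Cdkn1a, and Maff, a small MAF factor, at −1.34 (SE 0.26). Mycn, of the MYC family, had a change of 1.16 (SE 0.44, adjusted p = 0.651), with groups that did not overlap, and 0.40 and 0.35 on its other 2 probe sets. Control replicate 1 stood farthest from its group, and 6 genes were called without it; 2 each were called without control replicate 3 or without KO replicate 1 or 2, Synpo2 among the last (adjusted p = 0.0185). Removing that control array together with control replicate 3 of day 21, after the data were seen, gave 3 calls, all lower.

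At day 21 megakaryocyte and erythroid genes stood highest in KO relative to control. Of 19 megakaryocyte genes 16 were higher, with a median log2 change of 1.03 (camera adjusted p = 5.5e-07; adjusted p = 0.0337 with an estimated correlation). None passed over all genes and 8 were higher when adjusted over the list alone. Among these, the platelet chemokines Ppbp and Pf4 had changes of 2.66 (SE 0.43) and 3.23 (SE 0.90), the integrin gene Itga2b 1.67 (SE 0.28), and the platelet receptor gene Gp1bb 2.29 (SE 0.58). Of 20 erythroid genes 19 were higher, with a median of 1.17 (camera adjusted p = 2.9e-07; adjusted p = 0.0836 with an estimated correlation). The transcription factor gene Gfi1b, at 1.65 (SE 0.32), and the water channel gene Aqp1, at 2.61 (SE 0.56), passed over the list alone.

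Other lists moved less at day 21. G2/M genes were higher in 42 of 53, with a median of 0.34 (camera adjusted p = 7.9e-04; adjusted p = 0.473 with an estimated correlation), and none passed over the list alone. Multipotent progenitor genes had a median of 0.59 (camera adjusted p = 0.00318; adjusted p = 0.205 with an estimated correlation), with Wfdc17 at 3.98 (SE 0.69) past the list's own threshold. Ribosome biogenesis genes had a median of 0.35 (camera adjusted p = 0.00514; adjusted p = 0.191 with an estimated correlation), and Pes1 had 2.52 (SE 0.63). That call was lost without control replicate 1 (median 0.31, adjusted p = 0.0673). Interferon-stimulated genes had a median of 0.49 (camera adjusted p = 0.0194; adjusted p = 0.614 with an estimated correlation), and Usp18, a negative regulator of interferon signalling, had 2.16 (SE 0.49). Without KO replicate 4 their median was 0.29 (adjusted p = 0.603), and without control replicate 1 it was 0.43 (adjusted p = 0.0673). With the ratio of 3' to 5' control signals as a covariate the interferon list lost its call (median 0.14, adjusted p = 0.377). With the share of probe sets at the floor as a covariate, the G2/M, multipotent progenitor and interferon lists lost their calls, with medians of 0.26, 0.48 and 0.24. HSC identity genes had a median of −0.03 at day 21 and −0.02 at day 7 and were called at neither.

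limma called 3 genes at day 21, all higher in KO, and 1690 genes had an unadjusted p under 0.05. Ache, which encodes acetylcholinesterase, rose by 3.19 on the log2 scale (SE 0.37, adjusted p = 0.0139), from a mean log2 intensity of 6.01 ± 0.91 (SD, n = 4) to 9.20 ± 0.50 (SD, n = 4). Adgrg3, an adhesion G protein-coupled receptor, rose by 2.93 (SE 0.39, adjusted p = 0.0296), and Mvb12b, a subunit of the ESCRT-I sorting complex, by 2.61 (SE 0.36, adjusted p = 0.0309). The other 3 probe sets of Mvb12b gave 0.45, 1.24 and 1.16, and none of these passed. None of the 3 genes overlapped between the groups. Ache kept its call whichever of the 8 day 21 arrays was left out and in 12 of 14 other settings, Adgrg3 in 8 and Mvb12b in 5. With only the arrays compared none of the 3 passed (adjusted p = 0.174, 0.173 and 0.174), nor with the replicate number and RNA quality together (0.231, 0.231 and 0.288). Adgrg3 lost it without KO replicate 2 (adjusted p = 0.0603) or control replicate 3 (adjusted p = 0.0560), and Mvb12b without KO replicate 2, 3 or 4 (adjusted p = 0.0603, 0.105 and 0.104) or control replicate 3 (adjusted p = 0.0560). The smallest p-values among lower genes belonged to Ccnd2, which encodes cyclin D2, at −0.69 (SE 0.11, adjusted p = 0.0536), Cebpa, and Fzd8, a Wnt receptor gene, at −2.63 (SE 0.45, adjusted p = 0.0540). Without control replicate 2 these 3 passed, with adjusted p = 0.0396, 0.0307 and 0.0491. Other probe sets of Ccnd2 had larger falls, from −1.05 to −1.60, and none passed. Mycn had 0.60 (SE 0.38, adjusted p = 0.640), with overlapping groups, and −0.14 and 0.38 on its other 2 probe sets. The 4 control arrays were the most variable group, with a median gene SD of 0.70 against 0.47 in KO. The count was 42 without control replicate 2, 12 without control replicate 1, 10 without control replicate 4, 5 without KO replicate 1 and 1 without KO replicate 2; it was 5 without the array farthest from its group in each control group and 1 with the floor covariate.

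**Figure D2:**
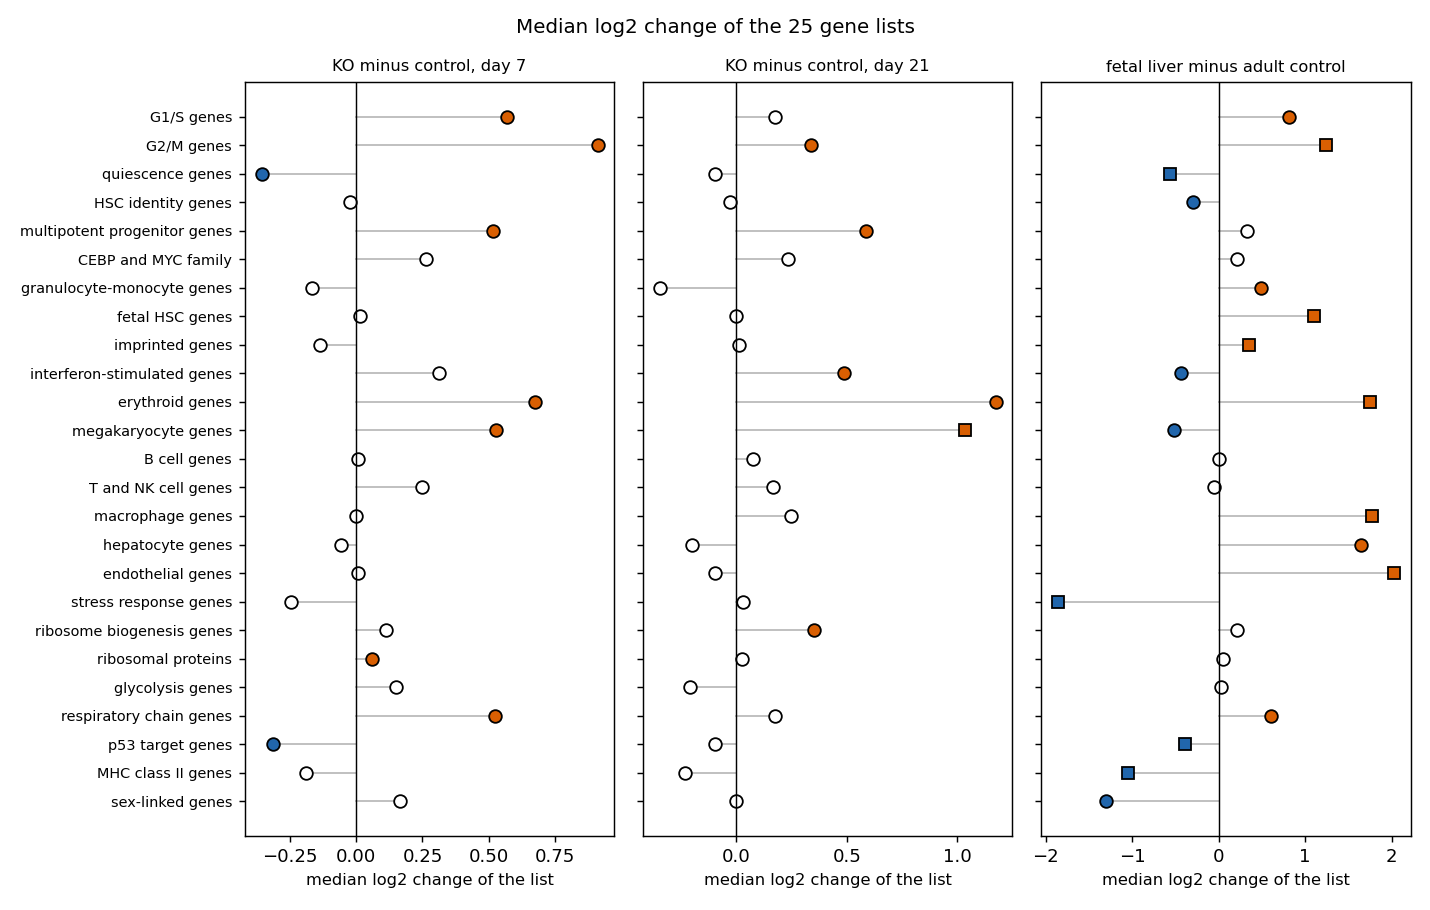
Median log2 change (horizontal axis) of each of the 25 gene lists (vertical axis) for KO minus control at day 7 and day 21 and for fetal liver minus adult control; the horizontal scales differ. Filled symbols passed camera at the preset correlation, orange where higher and blue where lower, open symbols did not, and squares mark an adjusted p under 0.05 with the estimated correlation. At day 21 only the megakaryocyte list among the KO lists is a square, at 1.03.

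The difference between both KO effects was tested directly. No gene was called, with a smallest adjusted p of 0.341, and 758 genes had an unadjusted p under 0.05. The unmoderated linear model also called 0. The smallest p-values belonged to 4833407H14Rik, at 4.10 (SE 0.68), Ache, at 3.22 (SE 0.57), and Thoc5, at 2.86 (SE 0.51), among positive values. Among negative values they belonged to Pigt, at −2.06 (SE 0.43), Rasgrp1, at −1.48 (SE 0.33), and Aacs, at −1.31 (SE 0.31; −1.42 and −0.10 on its other 2 probe sets). Ache passed without control day 21 replicate 3, at 3.61 (adjusted p = 0.0287). Pigt had 0.0127 when all its probe sets were averaged. Other probe sets of Rasgrp1, near the floor, had −0.11, −0.12 and −0.26. The KO effect on G2/M genes was lower at day 21 than at day 7 by a median of −0.47 (camera adjusted p = 0.00295; adjusted p = 0.662 with an estimated correlation). That on respiratory chain genes differed by −0.36 (camera adjusted p = 2.5e-04; adjusted p = 0.662 with an estimated correlation). The G2/M call was lost without KO day 21 replicate 2 (median −0.35, adjusted p = 0.0515), KO day 7 replicate 3 (−0.46, adjusted p = 0.134) or control day 7 replicate 1 (−0.34, adjusted p = 0.0640). The megakaryocyte list did not differ between days by this test, with a median of 0.43 (adjusted p = 0.165). Across genes, which are not independent replicates, both KO effects correlated with r = 0.231 and Spearman's rho = 0.228, with 58.0% of genes of the same sign. These effects share no array.

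Fetal liver HSCs differed from adult controls in 613 genes, of which 316 were higher and 297 lower, the comparison the study's title places at the acquisition of adult quiescence. Genes of fetal growth control were higher. Of 15 measured fetal HSC genes 5 were called, all higher (camera adjusted p = 8.2e-07; adjusted p = 0.0020 with an estimated correlation). Igf2, a fetal growth factor gene, rose by 5.02 on the log2 scale (SE 0.37, adjusted p = 3.9e-06). Hmga2, a chromatin protein gene downstream of the Lin28b and let-7 pathway, rose by 4.95 (SE 1.15, adjusted p = 0.0305), and the RNA-binding protein gene Igf2bp3 by 3.34 (SE 0.41, adjusted p = 3.5e-04). Among 25 imprinted genes 7 were called, all higher (camera adjusted p = 3.2e-05; adjusted p = 0.0295 with an estimated correlation), with Mest at 5.31 (SE 0.85) and Peg3 at 2.67 (SE 0.22). The call of this Hmga2 probe set was lost without any 1 of the 3 fetal arrays or of control day 7 replicates 1 and 2, with an adjusted p of 0.0987 at most. Over all probe sets, 2 others of Hmga2 passed, at 5.66 (adjusted p = 0.00235) and 5.13 (adjusted p = 1.3e-04), and a dim one did not, at 1.22 (adjusted p = 0.165). On fetal replicates 1, 2 and 3 the mean log2 intensity was 7.41, 7.79 and 8.02 for the fetal HSC list and 6.99, 7.73 and 7.97 for the imprinted list, in the same order as for the hepatocyte and endothelial lists below.

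Cell cycle genes were also higher on the fetal arrays. Genes of other cell types were higher there too, as given below, and whether such cells carry part of this rise was not tested. The G2/M list had a median of 1.24, with 8 of 53 called higher and 26 higher when adjusted over the list alone (camera adjusted p = 1.6e-11; adjusted p = 0.0185 with an estimated correlation). Ccna2, which encodes cyclin A2, rose by 2.47 (SE 0.50, adjusted p = 0.0134), Aurka, a mitotic kinase gene, by 2.76 (SE 0.66, adjusted p = 0.0355), and the proliferation marker Mki67 by 1.22 (SE 0.24, adjusted p = 0.0122). The G1/S list had a median of 0.81 (camera adjusted p = 3.9e-05; adjusted p = 0.0513 with an estimated correlation), with Uhrf1 called at 1.94 (SE 0.45). Respiratory chain genes were higher in 35 of 36, with a median of 0.60 (camera adjusted p = 3.2e-07; adjusted p = 0.0736 with an estimated correlation), and Atp5o was called at 1.28 (SE 0.25). Mycn rose by 1.47 (SE 0.37, adjusted p = 0.0457; its other 2 probe sets had 1.38 and 0.29 and did not pass) and Cebpa fell by 2.08 (SE 0.47, adjusted p = 0.0246). The call of Mycn was lost with any 1 of 9 of the 10 arrays left out, up to adjusted p = 0.189 without fetal replicate 1, and that of Cebpa without fetal replicate 1 (adjusted p = 0.0808) or 2 (adjusted p = 0.125). Another, dim probe set of Aurka had −0.11. Aurka lost its call for 6 arrays (adjusted p = 0.137 without fetal replicate 1), Uhrf1 for 3 (0.138 without fetal replicate 3), Ccna2 without fetal replicate 2 (0.0712) and Atp5o without fetal replicate 3 (0.0581).

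Stress response, quiescence and MHC class II genes were lower on the fetal arrays. All adult arrays came from day 7 or day 21 after pIpC, and the labels give no pIpC day for fetal liver. In the whole fetal comparison, stage, tissue and pIpC could therefore not be separated. Of 22 immediate early and heat shock genes, which rise during tissue dissociation and sorting, 17 were called and all 17 were lower, with a list median of −1.86 (camera adjusted p = 6.9e-28; adjusted p = 0.0020 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, fell by 5.25 (SE 0.60, adjusted p = 2.0e-04), and Egr1 by 2.78 (SE 0.26); the change of the heat shock gene Hspa1b was −4.998 (SE 0.94, adjusted p = 0.00897), and its other 2 probe sets had −3.03 and −3.44 without passing. Quiescence genes had 8 of 23 called lower, with a median of −0.56 (camera adjusted p = 1.7e-06; adjusted p = 0.0111 with an estimated correlation). Cdkn1a fell by 3.43 (SE 0.29, adjusted p = 1.3e-05), and the early-response nuclear receptor genes Nr4a1 and Nr4a2 by 3.76 (SE 0.48) and 3.60 (SE 0.63). Other Nr4a2 probe sets had −4.20, −3.34 and −2.49 and passed, or −0.22 and −0.09 and did not. Egr1, Nr4a1 and Btg2 belong to the stress list as well, so the 2 lists are not separate evidence. Of 21 p53 targets 3 were called lower, Plk3 among them at −2.28 (SE 0.44) (camera adjusted p = 1.3e-04; adjusted p = 0.0057 with an estimated correlation). MHC class II genes had a median of −1.05, with 3 of 10 called lower (camera adjusted p = 3.3e-05; adjusted p = 0.0083 with an estimated correlation), led by H2-Aa at −3.58 (SE 0.45) and H2-Ab1 at −2.26 (SE 0.48). Over all probe sets, others of H2-Aa had −2.66, which passed, and −1.23, which did not. Those of H2-Ab1 had −0.93, which passed, and −0.98, which did not. H2-Ab1 lost its call without fetal replicate 2 (adjusted p = 0.0872) or 3 (adjusted p = 0.0966), and Plk3 without fetal replicate 3 (adjusted p = 0.0559).

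HSC identity genes were lower, with 6 of 30 called and a median of −0.30 (camera adjusted p = 0.00153; adjusted p = 0.0672 with an estimated correlation). The niche factor gene Angpt1 fell by 2.06 (SE 0.18, adjusted p = 1.8e-05; its other probe set had −0.76 and did not pass) and Sult1a1 by 2.76 (SE 0.66); the change of the transcription factor gene Gata2 was −1.594 (SE 0.19). Sult1a1 lost its call with any 1 of 7 of the 10 arrays left out, up to adjusted p = 0.145 without fetal replicate 1. The mean log2 intensity of the HSC identity list was 8.57, 8.89 and 9.18 on fetal replicates 1, 2 and 3. Fetal replicate 3 lay within the adult control range, which ran from 9.05 to 9.59. Robo4, Esam and Tek belong to the endothelial list as well. Megakaryocyte genes had a median of −0.51 (camera adjusted p = 0.0236; adjusted p = 0.145 with an estimated correlation), and the integrin gene Itgb3 fell by 3.79 (SE 0.58, adjusted p = 0.00207). Interferon-stimulated genes had a median of −0.43 with no member called over all genes (camera adjusted p = 0.00272; adjusted p = 0.194 with an estimated correlation). Without fetal replicate 1 neither list was called (adjusted p = 0.140 and 0.0688). The largest falls outside the lists were those of the class I gene H2-Q5, at −5.54 (SE 0.26) on 1 of its 2 probe sets and 0.14 (adjusted p = 0.668) on the other, the transcription factor genes Bhlhe40, at −5.40 (SE 0.28), and Klf9, at −5.32 (SE 0.77), and Rgs1, a regulator of G protein signalling, at −5.31 (SE 0.36). Aldh1a1, an aldehyde dehydrogenase gene, was at the floor on all 3 fetal arrays and at least 32.0-fold lower there.

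Genes of other fetal liver cell types were higher on the fetal arrays. Of 17 macrophage genes 5 were called, all higher, with a median of 1.78 (camera adjusted p = 2.2e-09; adjusted p = 8.9e-04 with an estimated correlation). The complement gene C1qb, at the floor on all day 21 controls, rose by at least 5.999 (SE 0.64, adjusted p = 9.2e-05) and the mannose receptor gene Mrc1 by 4.94 (SE 0.44). All 18 endothelial genes had positive values and 8 were called, with a median of 2.02 (camera adjusted p = 1.2e-11; adjusted p = 0.0185 with an estimated correlation). Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, rose by 5.64 (SE 0.48) and Cdh5, for VE-cadherin, by 4.37 (SE 0.76). All 16 hepatocyte genes had positive values, 4 were called, and all 16 passed when adjusted over the list alone, with a median of 1.65 (camera adjusted p = 9.1e-11; adjusted p = 0.0645 with an estimated correlation). Alb, for albumin, rose by 3.38 (SE 0.85, adjusted p = 0.0440) and Apoa1 by 2.89 (SE 0.41). Alb lost its call with any 1 of 7 of the 10 arrays left out, up to adjusted p = 0.186 without fetal replicate 3. The mean log2 intensity of the hepatocyte list was 5.76, 8.19 and 8.22 on fetal replicates 1, 2 and 3, against 5.64 over the adult controls. That of the endothelial list was 7.11, 8.70 and 9.43, against 6.25.

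Blood lineage genes moved as well. Of 20 erythroid genes 8 were called higher, with a median of 1.74 (camera adjusted p = 1.7e-11; adjusted p = 0.0083 with an estimated correlation). The red cell anion exchanger gene Slc4a1 rose by 5.77 (SE 0.84) and Klf1 by 4.11 (SE 0.72). Granulocyte-monocyte genes had 3 called higher and 2 lower of 28, with a median of 0.49 (camera adjusted p = 0.0236; adjusted p = 0.279 with an estimated correlation). The neutrophil granule genes Ngp and Camp rose by 4.32 (SE 0.84) and 3.71 (SE 0.76). Without fetal replicate 1 this list lost its call (median 0.35, adjusted p = 0.523), as did Camp (adjusted p = 0.0685), and without fetal replicate 2 Ngp did (adjusted p = 0.0561). Stfa3, a stefin gene, was at the floor on all adult arrays and at least 72.2-fold higher in fetal liver, and Acp5, a phosphatase gene of macrophages and osteoclasts, rose by 5.61 (SE 0.73). Single called members of other lists were Wfdc17 of the progenitor genes, at 2.62 (SE 0.67), Lat of the T and NK cell genes, at −1.44 (SE 0.35), Ddx21 of ribosome biogenesis, at −1.37 (SE 0.25; −0.61 and no call on its other probe set), and Hk2 of glycolysis, at −1.55 (SE 0.33). Lat lost its call for 6 left-out arrays (adjusted p = 0.181 without fetal replicate 2), Wfdc17 for 5 (0.168 without fetal replicate 1) and Hk2 for fetal replicates 2 (0.0916) and 3 (0.0974). These 4 lists, with medians of 0.33, −0.06, 0.21 and 0.03, were not called, nor were the B cell, ribosomal protein and C/EBP and MYC family lists, whose medians were 0.00, 0.06 and 0.21. Against control day 7 alone 402 genes were called, and against control day 21 alone 455; 241 were called when the fit held only the fetal and control arrays.

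**Figure D3:**
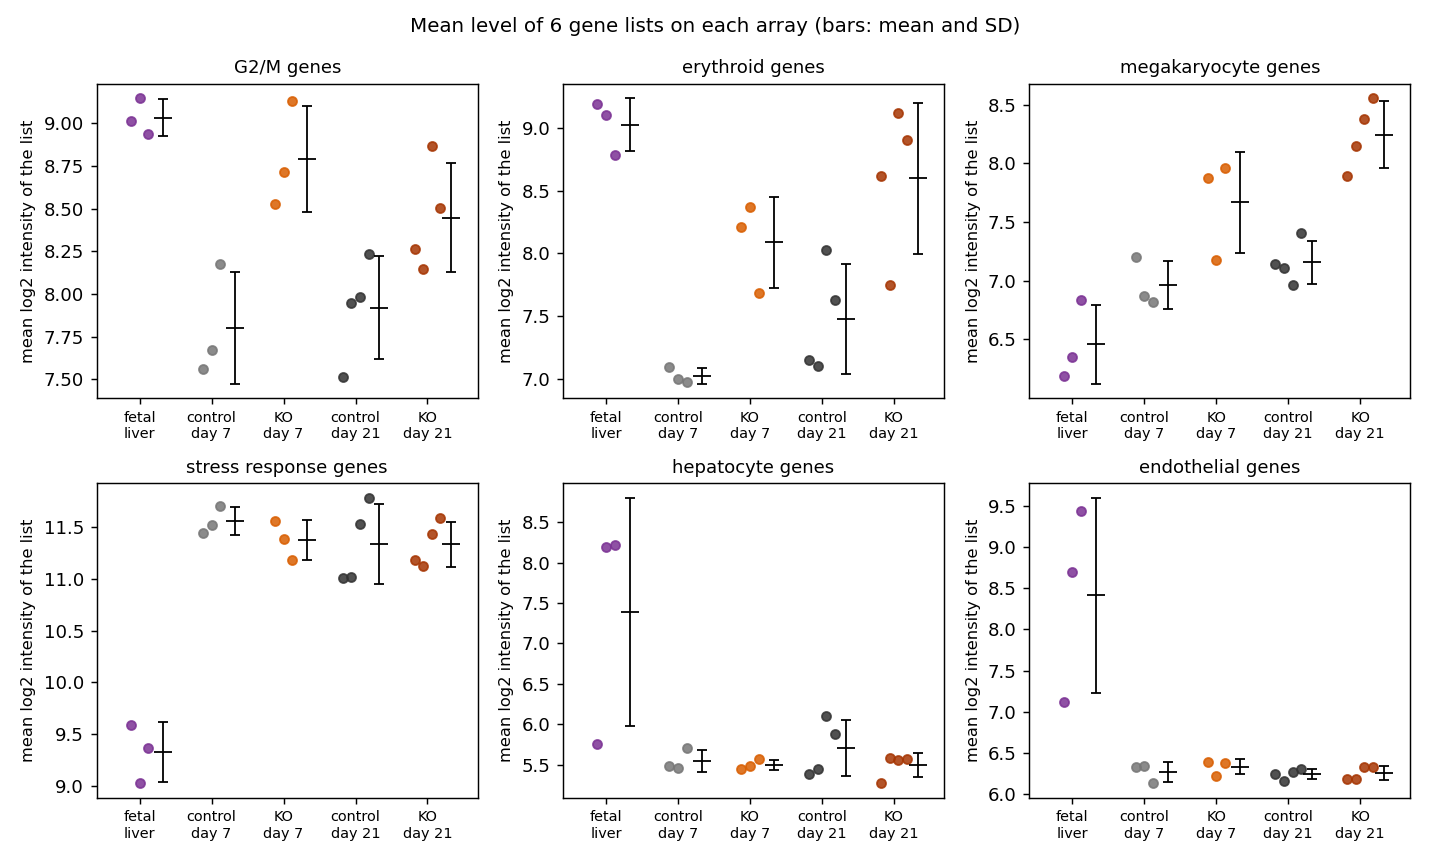
Mean log2 intensity (vertical axis, scales differ) of 6 gene lists on each of the 17 arrays, by group (horizontal axis). Points are arrays, and bars beside them give the group mean and SD. Fetal replicate 1 lies at 5.76 for hepatocyte genes, near the adult controls, and the other 2 fetal arrays lie at 8.19 and 8.22.

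KO effects were set against fetal effects measured with the controls of the other day. The KO effect at day 7 correlated with the difference between fetal liver and control day 21 with r = 0.202 and rho = 0.201 across genes, and the KO effect at day 21 with that between fetal liver and control day 7 with r = 0.0876 and rho = 0.0728. Simulated unchanged groups gave means of −7.8e-05 and −3.0e-04, which is fixed by construction where genes are drawn independently and no array is shared. Real genes may vary together, so these values do not show how large r can become by chance. With shared controls r was 0.504 and 0.465, where unchanged groups gave 0.4996 and 0.462. The covariances were 0.248 and 0.224, where unchanged groups gave 0.143 and 0.107. The simulation gave all groups 1 spread per gene, although control day 21 was the most variable group, with a median gene SD of 0.70. It may therefore understate the covariance from shared controls at day 21, and no excess is read from it. Of the 200 genes lowest in fetal liver, 138 were lower in KO at day 7, with a median of −0.43 (camera p = 2.2e-09; p = 5.1e-04 with an estimated correlation). The 200 genes highest in fetal liver had a median of 0.21 at day 7 (camera p = 0.0170; p = 0.142 with an estimated correlation) and of 0.26 at day 21 (camera p = 5.5e-04; p = 0.0877 with an estimated correlation). At day 21 the 200 genes lowest in fetal liver had a median of −0.14 and no call (camera p = 0.178; p = 0.394 with an estimated correlation). With the floor covariate the day 21 correlation was 0.0178 and the fetal-high set lost its call (median 0.10, p = 0.188).

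Control day 21 was set against control day 7 as the background change with time. The Y-linked genes Eif2s3y and Kdm5d were lower at day 21, by 4.72 (SE 0.25, adjusted p = 7.8e-07) and 4.76 (SE 0.67, adjusted p = 0.0287) on the log2 scale, and Eif2s3y was at the floor on all 4 day 21 controls, at least 26.3-fold lower. Xist, the transcript of the inactive X chromosome, had a change of 7.41 (SE 1.15, adjusted p = 0.0502). This SE uses the spread of all 5 groups, and KO at day 7 had an SD of 3.87 for Xist. The controls had SDs of 0.36 at day 7 and 0.15 at day 21 and did not overlap. Of 4 sex-linked genes measured, 2 were called lower (camera adjusted p = 0.0116; adjusted p = 0.0993 with an estimated correlation). All 3 controls and 2 of 3 KO arrays at day 7 had high Y-linked and low Xist signal, and all day 21 and fetal arrays had the reverse. KO day 7 replicate 1 had both, with an Xist intensity of 4893 and an Eif2s3y intensity of 130. Sex and day could therefore not be separated, and for fetal liver the control group of the same sex pattern was that of day 21; Eif2s3y, whose value of −2.36 came from control day 7 alone because all fetal and day 21 control arrays lay at the floor, and the sex-linked list (median −1.31, camera adjusted p = 0.0339; adjusted p = 0.0736 with an estimated correlation) were lower in fetal liver against both controls together. The fetal call of the list was lost without fetal replicate 1 (adjusted p = 0.0606), fetal replicate 3 (0.0546) or control day 21 replicate 3 (0.0507), and its call between control days without control day 21 replicate 2 (0.0550). The other 2 probe sets of Kdm5d had −1.23 and −1.89 and did not pass. Kdm5d lost its call with any 1 of 6 of the 7 arrays left out, up to adjusted p = 0.108 without control day 7 replicate 2. Its spread in the fit also includes KO at day 7, with an SD of 2.20. The controls had SDs of 0.44 at day 7 and 0.13 at day 21 and did not overlap.

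The other called genes were 4833407H14Rik, at −3.61 (SE 0.48), the histone gene H2aw, at −3.53 (SE 0.53), and Golga7, at −1.37 (SE 0.19), which lay outside the rule and was named after its values were seen; all were lower at day 21. Among higher genes the next smallest p-values were those of Atxn2, at 1.27 (SE 0.22), and Krt42, at 0.84 (SE 0.16), and neither was called. Stress response genes had a median of −0.22 (camera adjusted p = 0.0467; adjusted p = 0.824 with an estimated correlation), with Fos at −1.03 (SE 0.27), and respiratory chain genes a median of 0.30 (camera adjusted p = 0.0440; adjusted p = 0.824 with an estimated correlation). The other probe set of H2aw had −1.92 and did not pass. With 1 array left out H2aw lost its call for 6 of the 7 arrays (adjusted p = 0.142 without control day 21 replicate 3) and 4833407H14Rik for 4 (0.0746 without the same array). The calls of the stress response and respiratory chain lists were each lost with any 1 of 5 of the 7 arrays left out. The count of called genes was 1 without control day 7 replicate 2, 3 without control day 21 replicate 3, 8 without control day 7 replicate 3 or control day 21 replicate 2, and 11 without control day 21 replicate 1.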

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

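The tests of sex-linked transcripts and of other cell types on the fetal arrays were chosen after the result was seen, as was the form of the fetal regrouping test, which replaced regroupings that also shuffled the control days once their output had been seen. So were the 2 settings of the array tests for the KO lists (a covariate for the floor and the array farthest from its group left out of each control group), whose bounds were set before their values were computed.

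Day 21 arrays that stood far from the other 3 of their group were looked for in 68 groups of 4 values, and 7 were found; chance gives about 1 in 20. The gap to the nearest array, as a share of the group's range, was 0.936 for Wfdc17 and 0.926 for H2aw, both highest in control replicate 2. It was 0.845 for Camp, highest in control replicate 4, and 0.934 for Pigt, lowest in control replicate 1. Mycn in KO replicate 3 had 0.897, at a log2 intensity of 10.3 against 9.10 on the nearest array. For Mrc1 and Kdm5d in the controls the share was 1, because 1 array lay just above the floor and the other 3 at it. The KO effect differed between days for G2/M genes by a median of −0.47 and for respiratory chain genes by −0.36, by camera on the interaction; with an estimated correlation neither held (adjusted p = 0.662). Among 9160 probe sets without a gene name here, 109 were called between fetal liver and adult control, 8 between both control days and 6 between KO and control at day 7; 0 were called between KO and control at day 21, where 579 had an unadjusted p under 0.05.

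Macrophage, endothelial, hepatocyte and erythroid genes were higher on the fetal arrays, although the sort required lineage-negative cells, which would remove mature blood cells, and Sca-1, c-Kit and CD150 without CD48, which would remove hepatocytes and most other cells outside the HSC gate. If such cells entered the sorts in differing amounts, list members would deviate together between the 3 fetal arrays. Their mean pairwise covariance lay at percentile 100 of 10000 random lists for hepatocyte and for endothelial genes, at 98.3 for macrophage genes and at 87.3 for erythroid genes, which lies between the bounds and leaves that list open. The random lists were matched on size and mean level alone, so genes regulated together within HSCs could reach such percentiles too. A high percentile therefore cannot tell admixture from regulation. Of 16 hepatocyte genes 0 and of 18 endothelial genes 3 belong to another list, and 10 of each were above the median probe set in adult controls; for 17 macrophage genes these were 1 and 2, and for 20 erythroid genes 2 and 16. Alb and Apoa1, abundant in hepatocytes, had mean log2 intensities of 9.88 and 9.65 in fetal liver. Expression by fetal HSCs themselves was not tested. For hepatocyte, endothelial and macrophage genes an admixture that differs between sorts may account for part of the signal. The same stays open for part of the rise of fetal HSC and imprinted genes, Igf2 and Mest among them, whose list means followed the same order over the fetal arrays; on replicate 1 they were 7.41 and 6.99, against 6.41 and 6.49 on the highest adult control.

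The excess of cell cycle and megakaryocyte-erythroid genes in KO coincided with fewer probe sets at the floor on KO arrays and with 2 control arrays far from their groups. With the floor share as a covariate the day 7 medians were 0.79 for G2/M and 0.96 for erythroid genes, and the day 21 medians 1.24 for megakaryocyte and 1.48 for erythroid genes. Without the 2 control arrays they were 0.79, 0.81, 0.87 and 1.23, and all these lists were still called at the preset correlation, which argues against either as the whole cause. In the main analysis only the megakaryocyte list passed with an estimated correlation (adjusted p = 0.0337), and the others did not (0.0808 and 0.0815 at day 7, 0.0836 at day 21). Without KO day 7 replicate 1 the day 7 G2/M median was 1.02, with a call at the preset correlation, which argues against its female RNA. RNA quality differed as well: at day 21 the log2 ratio of 3' to 5' control signals ran from −0.40 to 0.20 in control and from 0.19 to 0.30 in KO. With it as a covariate the megakaryocyte median was 0.99 (adjusted p = 1.9e-04) and the erythroid median 1.36 (adjusted p = 3.5e-07) at the preset correlation. A larger share of cycling or megakaryocyte-erythroid primed cells in the KO gate remains possible, as does a change within HSCs, and no test here separates them. The day 21 G2/M list lost its call with the floor covariate (median 0.26), so this reading does not extend to it.

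KO day 7 replicate 1 carried Xist and Y-linked transcripts together. Its Eif2s3y intensity was 130, between the highest array with female pattern, 16, and the lowest of the other 5 day 7 arrays, 310, and its Xist intensity was 4893, which a pool of male and female animals could give. Its Kdm5d intensity was 41.5, against 353 to 761 on those 5 arrays and 21.3 at most on arrays with female pattern, and Uty lay at the floor. Kdm5d stood lower relative to the other day 7 arrays than Eif2s3y did, so these genes do not agree on a male share, and none is given. A swap with a day 21 array is excluded, since Eif2s3y there was 16 at most, and a control under a KO label is excluded by its Cebpa intensity of 32.0 against 115 on the lowest control. No biological explanation was tested.

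Other groupings of the same arrays were counted. At day 21, 1 of 35 splits gave 3 or more called genes, the real one, with 2 as the highest other. That is the smallest share 35 splits can give, and the margin over the highest other is small. None of the 3 genes passed with only the arrays compared, and the count was 0 with replicate number and RNA quality together. Chance is therefore not firmly excluded for that count. For lists, 6 or more were called in 7 of 35 splits, with 7 as the highest other, so chance is not excluded for their number. At day 7 there are 10 splits, too few for a share under 0.05. All 10 gave 0 or more genes, with 2 as the highest other. Since the real count was 0, that share was fixed in advance. For lists, 1 gave 9 or more, with 5 as the highest other. For fetal liver, 1 of 100 drawn splits gave 613 or more genes, the real one, with 41 as the highest other. Chance is therefore excluded for that count. The real split alone also gave 18 or more lists, but with 16 as the highest other. That margin is small, so chance is not firmly excluded for the number of lists. Between control days, 5 of 35 splits gave 5 or more genes, with 21 as the highest other, and 4 gave 3 or more lists, with 3 as the highest other, so chance is not excluded. For the difference between KO effects, 100 of 100 drawn splits gave 0 or more genes, with 12 as the highest other. The real count was again 0, so that share was also fixed in advance. For lists, 51 gave 2 or more, with 12 as the highest other.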

How the results depend on the processing

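Settings with the array farthest from its group left out of each control group (here the 2 arrays), or with the share of probe sets at the floor as a covariate, were chosen after seeing the data; so were the list results under the other probe set choice, scalings, array weights, smaller fits and the joint block and RNA quality covariate. The cause of each change was not tested unless given.

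Genes called between KO and control at day 21 (3) numbered 19 with the mean of all probe sets, 12 with every probe set on its own, 11 with only genes above the median level, 9 without _s_at and _x_at probe sets and 5 without the 2 arrays. They numbered 1 with array weights, with the RNA quality covariate and with the floor covariate, and 0 with only the arrays compared. One array left out gave 1 to 42. Ache was called in 12 of 14 settings, Adgrg3 in 8 and Mvb12b in 5. At day 7 (0) the numbers were 2 with the mean of probe sets, 1 with every probe set, 1 with only the arrays compared, 3 without the 2 arrays and 0 to 6 with one array left out. For fetal liver (613) they were 1228 with every probe set, of which more were tested, 402 against control day 7 alone, 241 with only the arrays compared, and 419 to 691 with one array left out. Between control days (5) they were 20 with every probe set, 11 without the 2 arrays, 3 with the mean of probe sets, with genes above the median level and with only the arrays compared, 2 after centring, and 1 with array weights, the unmoderated model, the RNA quality covariate and the floor covariate; 1 to 11 with one array left out. For the difference of KO effects (0) they were 1 with every probe set, 4 without the 2 arrays and 0 to 2 with one array left out.

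Lists called at day 7 (9) numbered 0 with an estimated correlation and 5 with fry, which tests against no change, and 8 to 11 with one array left out. At day 21 (6) they numbered 1 with an estimated correlation, 3 with the floor covariate and 5 to 7 with one array left out. For fetal liver (18) they numbered 10 with an estimated correlation and 14 to 18 with one array left out. Between control days (3) they numbered 0 with an estimated correlation, 1 with fry and 0 to 4 with one array left out. For the difference of KO effects (2) they numbered 0 with an estimated correlation and with fry, 4 after centring and with the floor covariate, 5 with the RNA quality covariate, 1 without the 2 arrays and 1 to 4 with one array left out.

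The day 21 correlation with the fetal effect (0.0876) moved to 0.0178 with the floor covariate and 0.465 with shared controls, and that of day 7 (0.202) to 0.504 with shared controls, as shared arrays add covariance. With one array left out they ran from 0.0555 to 0.112 and from 0.166 to 0.217, and that between both KO effects from 0.185 to 0.260. The fetal-high set lost its call at day 21 with an estimated correlation (median 0.26) and the floor covariate (0.10), and at day 7 with an estimated correlation (0.21) and with 100 genes (0.0557); the fetal-low set gained one at day 21 with genes above the median level (−0.11). Centring each array shifted the median of all genes by −0.16 in KO at day 21 and by 0.16 between control days, and quantile normalization by −0.11 and 0.11. Of the called genes 3 were then higher and 1 lower at day 21 after centring, and 1 higher and 5 lower between control days after quantile normalization.

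Signs turned for Spi1, uncalled throughout, which ran from −0.46 to 0.31 at day 21 and from −0.33 to 0.0725 in fetal liver with one array left out; for Atxn2 (−0.998 without _s_at and _x_at probe sets) and Pigt (0.0127 with the mean of probe sets); and for the sex-linked list with genes above the median level, where Xist alone was left (7.41 between control days, 3.67 in fetal liver). Of the other results for single genes, 890 under other settings and 586 with one array left out kept direction and side of the threshold, 110 and 81 lost their call and 12 and 5 gained one; for lists these were 466 and 303, 64 and 28, and 0 and 0.

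Deviations of arrays with the same replicate number correlated at 0.082 at most, with a mean of 0.010. For other pairs the maximum was 0.058 and the mean −0.0034. Of 17 arrays, 7 correlated best with an array of their own number. These correlations are small, and they do not exclude a pairing. With the number as a block 3 genes were called at day 21, 0 at day 7, 524 in fetal liver and 4 between control days. With block and RNA quality together 0 were called at day 21 and 1 between control days, and lists numbered 7 between control days and 6 for the difference of KO effects. Signal near the floor, where 20.4% to 25.2% of probe sets lay, limits changes of dim genes.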

Other observations

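The tests of the rest of each fetal set were planned before their values were computed; the granulocyte-monocyte genes named here were chosen after their values were seen.

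Genes of the granulocyte-monocyte lineage, many of them regulated by C/EBP factors, had mostly negative values in KO without passing a test. At day 21, 6 of 28 had positive values, with a median log2 change of −0.34 (camera adjusted p = 0.0540; adjusted p = 0.622 with an estimated correlation), and at day 7, 7 of 28, with a median of −0.17 (camera adjusted p = 0.0902). Mpo, for myeloperoxidase, had −2.71 (SE 1.17) at day 7 and −2.16 (SE 1.01) at day 21, with adjusted p = 0.706 and 0.504. Elane, for neutrophil elastase, had −1.10 (SE 0.93) and −1.17 (SE 0.81). At day 21, 3 members had an unadjusted p under 0.05 with positive values, Ms4a3 at 1.67 (SE 0.61), Csf2rb at 1.67 (SE 0.71) and Cd14 at 0.81 (SE 0.36), and 1 with a negative value, Klf4 at −1.01 (SE 0.31). The fetal HSC genes, which were higher in fetal liver, had medians of 0.02 and 0.00 in KO at day 7 and day 21, with no call.

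The fall of fetal-low genes in KO at day 7 was tested for dependence on stress genes. Without 12 members of the stress, quiescence and p53 lists, the remaining 188 of 200 genes still had a median of −0.38 (camera p = 1.0e-08 at the preset correlation). So few genes were removed that this does not settle whether a stress program carries the fall. The rise of fetal-high genes at day 21 was tested in the same way. Without 43 members of the cell cycle, erythroid, macrophage, hepatocyte, endothelial and granulocyte-monocyte lists, the remaining 157 genes had a median of 0.23 (camera p = 8.2e-04 at the preset correlation). Genes of these cell types outside the lists were not removed. The result therefore does not settle whether other cell types carry the rise. The estimated correlation ended the call of the whole day 21 set (median 0.26, p = 0.0877), as did the share of probe sets at the floor as a covariate (median 0.10, p = 0.188), which also took the day 21 correlation with the fetal effect from 0.0876 to 0.0178.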
